A study of Homo sapiens with 8 samples.

How the data were processed

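RNA sequencing was measured in 8 tumors grown from HCC1937 cells, an established human triple-negative breast cancer line, in the mammary fat pad of NCG mice, an immunodeficient strain. The labels put 4 tumors in a group treated with nicotinamide mononucleotide (NMN, a precursor of NAD+, at 500 mg/kg/day) and 4 in a Vehicle group. Total RNA came from whole tumor tissue, and the labels' protocols mention both a capture step against ribosomal RNA and a selection with oligo(dT) beads. No sequencing batch, date or strandedness is given in the sources used here.

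The values used are TPM per gene, transcript abundances scaled to a fixed total per library, as deposited by the authors in 1 table of all 8 tumors, with the unit given per the file headers. The submitters' processing notes name HISAT2 2.1.0, Bowtie2 2.2.5, RSEM 1.2.8 and the human build GRCh38.p13, without saying which tool did which step. How reads from mouse tissue were handled is not given in the sources used here, so reads of mouse transcripts that also align to human genes can be part of any value. The table lists 18164 genes by symbol and Entrez identifier, of which 183 are at 0 in every library, and each library sums to 1000000. TPM keeps no record of read depth, so the depth of each library is unknown and no counting interval is given. The number of genes above 0 ran from 16451 to 16662 per library. None of the 13 protein-coding genes of the mitochondrial genome was among the genes analysed here.

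Genes entered the test when TPM was at least 1 in at least 4 of the 8 libraries, which left 13358 genes. The test was the moderated linear model of limma 3.58.1 in R 4.3.3 with a mean-variance trend, on log2(TPM + 1), with group as the only term, two-sided, and with Benjamini-Hochberg adjustment at 0.05. Fold changes are NMN over Vehicle on the log2(TPM + 1) scale, which understates the change of genes with low values. They are given as the estimate ± its standard error, and TPM levels as the mean ± SD of the 4 tumors of a group (n = 4). Single values were also compared by an exact two-sided permutation test of the difference of mean log2(TPM + 1), where the smallest p that 4 tumors against 4 allow is 0.0286.

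Gene lists were compared with all other tested genes by limma's camera with a preset correlation between genes of 0.01, adjusted over the lists tested. Of 42 lists, 40 had the required 4 tested members. Beside this test stand camera with an estimated correlation, limma's fry, and an exact permutation test of the list score, which is the mean over members of the deviation from the 8-library mean of log2(TPM + 1). Counts of members adjusted over the list alone use the limma p-values of that list's members only.

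The tests, the lists, the rule for the genes named and most other settings tried were chosen before the data were examined. The rule names 12 genes per direction, first those that passed the test with no overlap between groups and then, where too few did, those with the smallest unadjusted p, all with a mean of at least 5 TPM in the higher group. It also names SIRT1, SHC1, NAMPT, NMNAT1, NMNAT2, NMNAT3, NMRK1, NNMT and CD38 always, up to 3 members of each list with the smallest unadjusted p, and any member needed to describe a list. These other settings were pseudocounts of 0.1 and 5, no filter and a filter at 5 TPM, median-of-ratios scaling and quantile normalization, no variance trend, a robust fit, library weights, the replicate number as a block, each library left out, and the estimated correlation. A correction for GC content and length, a fit with the level of the muscle list as a covariate, removal of the MTRNR2L genes with rescaling to 1000000, and the permutation of list scores were added after the data were seen.

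Gene positions and transcript sequences are from GENCODE 29 on GRCh38. GC content and length, taken from the same annotation, were found for 97.3% of tested genes and were fitted per library with polynomials of degree 3. The model was tested on simulated data for this comparison of 4 against 4, with 13358 genes, 200 of them changed, in 20 simulations. It recovered 46.3% of genes changed 1.5-fold, 93.7% of those changed 2-fold and 99.8% of those changed 4-fold, and 5.76% of its calls were false. In these data the noise was independent between genes, no structure was shared between samples, and changed genes had a mean above about 5 TPM. The shares therefore do not show that the real tumors lacked changes of 2-fold. In lists of 25 simulated genes with a correlation of 0.3 and no shift, camera with the preset correlation called 32% and with the estimated correlation 0.5%.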

Results

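Whole-tumor RNA was compared between 4 tumors from mice given NMN and 4 from mice given vehicle, called NMN 1 to 4 and Vehicle 1 to 4. The labels do not state that each tumor came from a different mouse, so the p-values measure the spread between these 8 samples. The title of the series names NAD+ supplementation, metastasis, SIRT1 and p66Shc, a product of SHC1, and the comparison addresses how NMN altered the tumor transcriptome.

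Tumors of the NMN group had higher mean levels of genes of the hypoxia response, of glycolysis and of the immediate early response, and lower mean levels of skeletal muscle and interferon response genes. These differences were larger in NMN 1, NMN 2 and NMN 3 than in NMN 4, which lay within the range of the Vehicle tumors for most genes of each of these 5 lists. In other lists examined it lay within that range for 12 of 30 antioxidant genes, 51 of 72 oxidative phosphorylation genes and 16 of 18 basal markers. Such counts alone therefore do not set the 5 lists apart. NMN 4 still lay above the Vehicle range in 7 of the 20 immediate early genes and below it in 0. The 5 lists passed only with a preset correlation between genes, far below their estimated correlations, and not with an estimated correlation or fry. They did not pass by exact permutation either, which after adjustment over all lists could hardly pass with 4 tumors against 4. No single gene passed the test. SIRT1 and SHC1 did not pass either.

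For SIRT1, the NAD+-dependent deacetylase named in the title (chromosome 10, 67884669 to 67918390, plus strand), the level was 8.21 ± 1.08 TPM in NMN tumors and 7.70 ± 0.95 TPM in Vehicle tumors. The log2 fold change was 0.08 ± 0.15, with a 95% interval from -0.24 to 0.41 (adjusted p = 0.967). SHC1, which encodes p66Shc among other isoforms (chromosome 1, 154962298 to 154974395, minus strand), was at 55.5 ± 5.05 TPM in NMN tumors and 64.5 ± 7.89 TPM in Vehicle tumors. Its log2 fold change was -0.21 ± 0.11, with an interval from -0.46 to 0.04 (adjusted p = 0.819), and values per gene cannot tell its isoforms apart. The exact permutation test gave p = 0.486 for SIRT1 and p = 0.114 for SHC1.

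Among the enzymes that make NAD+, NAMPT, which forms NMN from nicotinamide, had a log2 fold change of -0.00 ± 0.16. The NMN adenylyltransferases NMNAT1, NMNAT2 and NMNAT3 had log2 fold changes of -0.15 ± 0.19, 0.33 ± 0.18 and -0.14 ± 0.14, and the nicotinamide riboside kinase NMRK1 one of -0.08 ± 0.13. Their adjusted p-values ran from 0.825 to 0.998. QPRT, which feeds quinolinic acid into NAD+ synthesis, stood at 14.8 ± 6.68 TPM in NMN tumors and 3.998 ± 2.12 TPM in Vehicle tumors, with no overlap between the groups and a log2 fold change of 1.65 ± 0.37 (adjusted p = 0.268). Of 23 tested NAD+ synthesis genes, 4 had a higher and 19 a lower mean in NMN tumors, the list did not pass (adjusted p = 0.288), and adjusted over the list alone QPRT was the 1 member that passed. The nicotinamide methyltransferase NNMT, at 0.618 and 0.925 TPM, and the NAD+ glycohydrolase CD38, at 0.263 and 0.283 TPM in NMN and Vehicle tumors, lay under the filter and were not tested. The lists of 10 NAD+-consuming enzymes, 7 sirtuins and 12 ShcA and RAS adaptor genes had median log2 fold changes of -0.03, 0.07 and 0.07 (adjusted p = 0.503, 0.581 and 0.487), and adjusted over the list alone 0 of their members passed. With 1 tumor left out these medians ran from -0.076 (without NMN 4) to 0.036 (without NMN 2), from 0.014 (without Vehicle 4) to 0.14 (without NMN 2) and from -0.026 (without Vehicle 2) to 0.12 (without NMN 2).

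Of 13358 genes tested, 0 passed at adjusted p under 0.05 with limma, and the smallest adjusted p was 0.221. At an unadjusted p under 0.05 stood 927 genes, 640 with the higher mean in NMN tumors and 287 with the lower, where 667.9 are expected with no effect. After quantile normalization the numbers were 640 and 514, and with the level of the muscle list as a covariate 797 and 99. Without NMN 4 they were 624 and 652, without NMN 3 379 and 189, and without NMN 1 474 and 189. The 4 NMN values did not overlap the 4 Vehicle values in 407 genes, or 3.05%, and chance gives 2.86%. Without NMN 4 the same test called 54 genes, 27 in each direction, and without Vehicle 3 it called 1, THRSP, with a log2 fold change of 1.69.

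The 12 genes with the smallest p among those higher in NMN tumors, none of which passed, were MSLN, ALDOC, ERRFI1, VGLL1, STAC2, CRABP1, PLAAT1, ENTPD2, CSF2RA, BNIP3, GSTM3 and S100A1. In each of them all 4 NMN tumors lay above all 4 Vehicle tumors, and the adjusted p was 0.221. MSLN, the cell surface glycoprotein mesothelin (chromosome 16, 760762 to 768865, plus strand), was at 32.8 ± 12.9 TPM against 10.8 ± 1.35 TPM, a log2 fold change of 1.45 ± 0.23. ERRFI1, a feedback inhibitor of EGFR, was at 92.1 ± 27.1 TPM against 38.4 ± 8.39 TPM, a log2 fold change of 1.22 ± 0.21. The retinoic acid binding protein gene CRABP1 was at 148 ± 9.46 TPM against 66.2 ± 26.4 TPM, and VGLL1, a partner of TEAD transcription factors, at 140.5 ± 18.7 TPM against 85.2 ± 10.8 TPM.

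The 12 genes with the smallest p among those lower in NMN tumors, none of which passed either, fell into a group of muscle genes, a group of mitochondrial pseudogene-like genes and 3 others. MYH4, MYLPF, ACTN2, TNNC2, ENO3 and MYOZ1 encode proteins of skeletal muscle and had log2 fold changes from -5.45 to -2.46. MTRNR2L1, MTRNR2L6 and MTRNR2L9 are nuclear copies of the mitochondrial 16S ribosomal RNA, for which reads cannot be assigned with certainty, and had log2 fold changes of -0.80 ± 0.15, -0.82 ± 0.14 and -0.65 ± 0.13. ALDH3A1, an aldehyde dehydrogenase, was at 16.1 ± 1.65 TPM against 25.6 ± 0.577 TPM, a log2 fold change of -0.64 ± 0.11. CAMK1, a calmodulin-dependent kinase, was at 6.60 ± 1.19 TPM against 11.1 ± 1.00 TPM, and OAS2, an interferon-induced oligoadenylate synthetase, at 22.1 ± 6.00 TPM against 36.7 ± 5.32 TPM. Adjusted p-values of the 12 ran from 0.221 to 0.268.

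**Figure D1:**
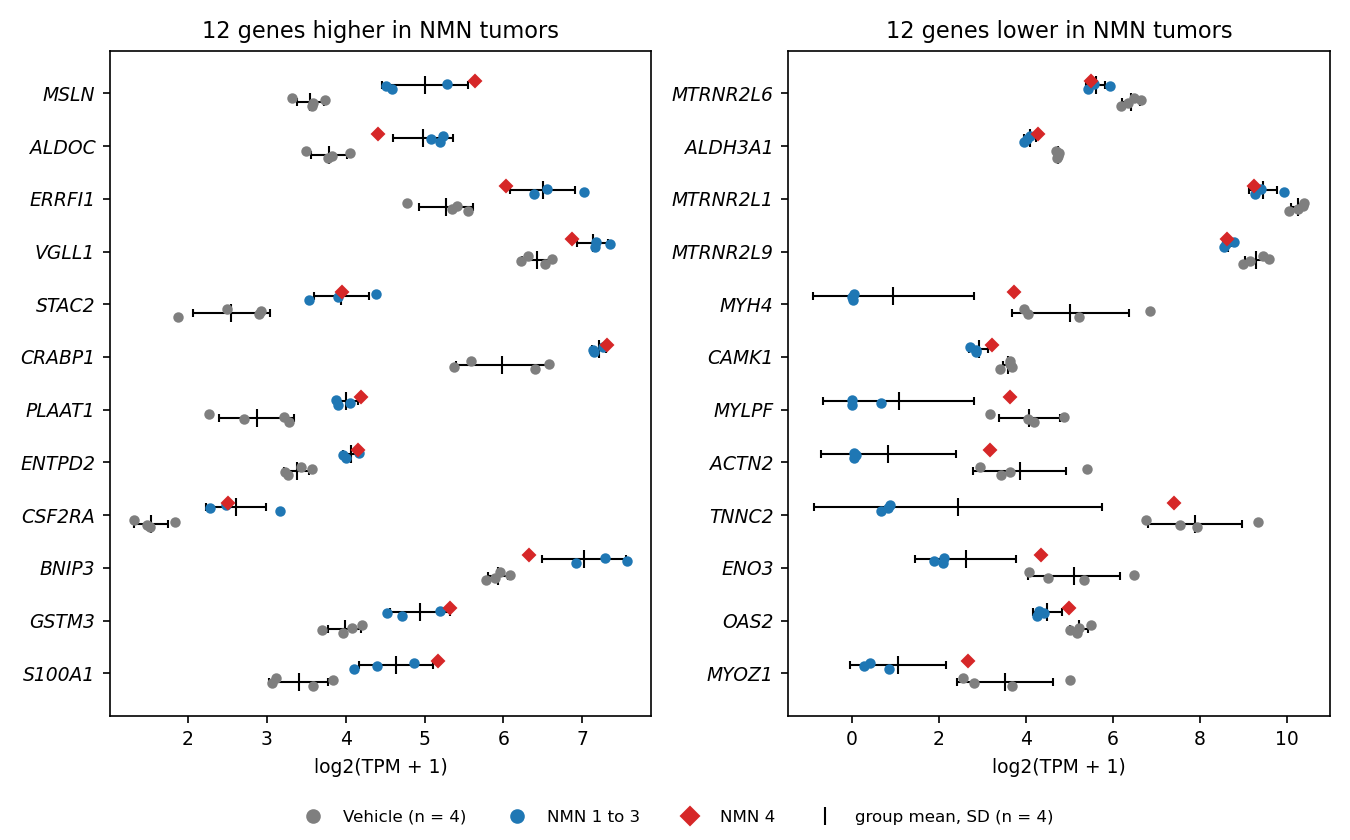
Each point is 1 tumor on a log2(TPM + 1) axis for the 12 genes per direction with the smallest p, with black bars for the mean and SD of 4 tumors per group. The 4 NMN tumors lie above the 4 Vehicle tumors in all 12 genes on the left, while NMN 4 lies with the Vehicle tumors for the muscle genes on the right, such as TNNC2 and MYOZ1. The exception is MYH4, where NMN 4 (12.29 TPM) lies just below the lowest Vehicle tumor (14.66 TPM).

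With the preset correlation, 8 of the 40 lists passed, 3 with higher and 5 with lower levels in NMN tumors. With an estimated correlation 0 of them did (smallest adjusted p = 0.367), nor did any by fry. The estimated correlations of the 8 lists ran from 0.15 for oxidative phosphorylation to 0.76 for skeletal muscle, with 0.48 for hypoxia, against the preset 0.01. The p-values with the preset correlation therefore overstate the evidence for these lists. By the exact permutation of the list score none passed, and the smallest adjusted p was 0.571. With 4 tumors against 4 this permutation test cannot go below p = 0.0286. After adjustment over 40 lists it could pass only if many lists reached that value, so its failure decides nothing. Without NMN 4 the preset test called 14 lists and the estimated correlation again none, with a smallest adjusted p of 0.154.

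All 25 tested hypoxia response genes, targets of the HIF transcription factors, had the higher mean in NMN tumors, with a median log2 fold change of 0.70 (adjusted p = 6.8e-19 with the preset correlation, and adjusted p = 0.367 with an estimated correlation). Adjusted over the list alone 15 passed, all higher, and over all genes 0. BNIP3, a mitophagy receptor, was at 136 ± 46.8 TPM against 60.1 ± 5.33 TPM, and DDIT4, an inhibitor of mTORC1, at 730.0 ± 163 TPM against 339 ± 171 TPM. ERO1A, an oxidase of the endoplasmic reticulum, had a log2 fold change of 0.78 ± 0.21. In 18 of the 25 genes NMN 1, NMN 2 and NMN 3 all lay above every Vehicle tumor, whereas NMN 4 lay above the Vehicle range in 5, within it in 19 and below it in 1. The list score was 0.29, 0.68 and 0.72 in NMN 1 to 3, -0.32 in NMN 4 and between -0.48 and -0.17 in the Vehicle tumors.

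Of 20 tested glycolysis genes, 18 had the higher mean in NMN tumors, with a median log2 fold change of 0.37 (adjusted p = 4.0e-08 with the preset correlation, and adjusted p = 0.539 with an estimated correlation). Over all genes 0 passed, and adjusted over the list alone 7 passed with higher levels and 1 with lower, PFKM, the muscle form of phosphofructokinase. The aldolase gene ALDOC was at 31.3 ± 7.56 TPM against 12.96 ± 2.18 TPM, the enolase gene ENO1 at 1425 ± 99.3 TPM against 1133 ± 92.1 TPM, and the isomerase gene GPI at 147 ± 22.8 TPM against 108 ± 8.75 TPM. Of the immediate early genes, 19 of 20 had the higher mean, with a median log2 fold change of 0.45 (adjusted p = 7.5e-10, and adjusted p = 0.367 with an estimated correlation). Of these 4 passed adjusted over the list alone, all higher, and 0 over all genes. The AP-1 genes JUN and FOS were at 130.1 ± 21.5 and 112 ± 62.6 TPM in NMN tumors against 86.3 ± 11.6 and 33.2 ± 13.3 TPM, and ATF3 had a log2 fold change of 0.55 ± 0.13. NMN 4 lay within the Vehicle range in 15 of the glycolysis genes and above it in 4, among them ALDOC, ENO1 and GPI. For the immediate early genes these numbers were 13 and 7, with JUN and ATF3 among those above. With the level of the muscle list as a covariate, none of the hypoxia, glycolysis and immediate early lists passed and camera turned their direction. The muscle score ran from -2.34 to -2.31 in NMN 1 to 3 and from 0.50 to 2.86 in the other tumors. That fit therefore compares mainly NMN 4 with the Vehicle tumors and decides nothing about these lists.

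Skeletal muscle markers had the lowest median of the 40 lists, -3.02 on the log2 scale over 15 tested genes (adjusted p = 8.2e-20 with the preset correlation, and adjusted p = 0.367 with an estimated correlation). The median was -5.06 with a pseudocount of 0.1 and -1.61 with one of 5. Adjusted over the list alone 14 passed with lower levels and 1, the myoglobin gene MB, with higher levels, and over all genes 0. ACTA1, the actin of skeletal muscle fibers, was at 263, 261, 1024 and 178 TPM in Vehicle 1 to 4, at 0.88, 0.36 and 1.16 TPM in NMN 1 to 3 and at 268 TPM in NMN 4. In 14 of the 15 genes NMN 1, NMN 2 and NMN 3 all lay below every other tumor. The list made up between 0.0463% and 0.269% of all TPM in the Vehicle tumors, 0.0700% in NMN 4 and between 0.0092% and 0.0096% in NMN 1 to 3.

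**Figure D2:**
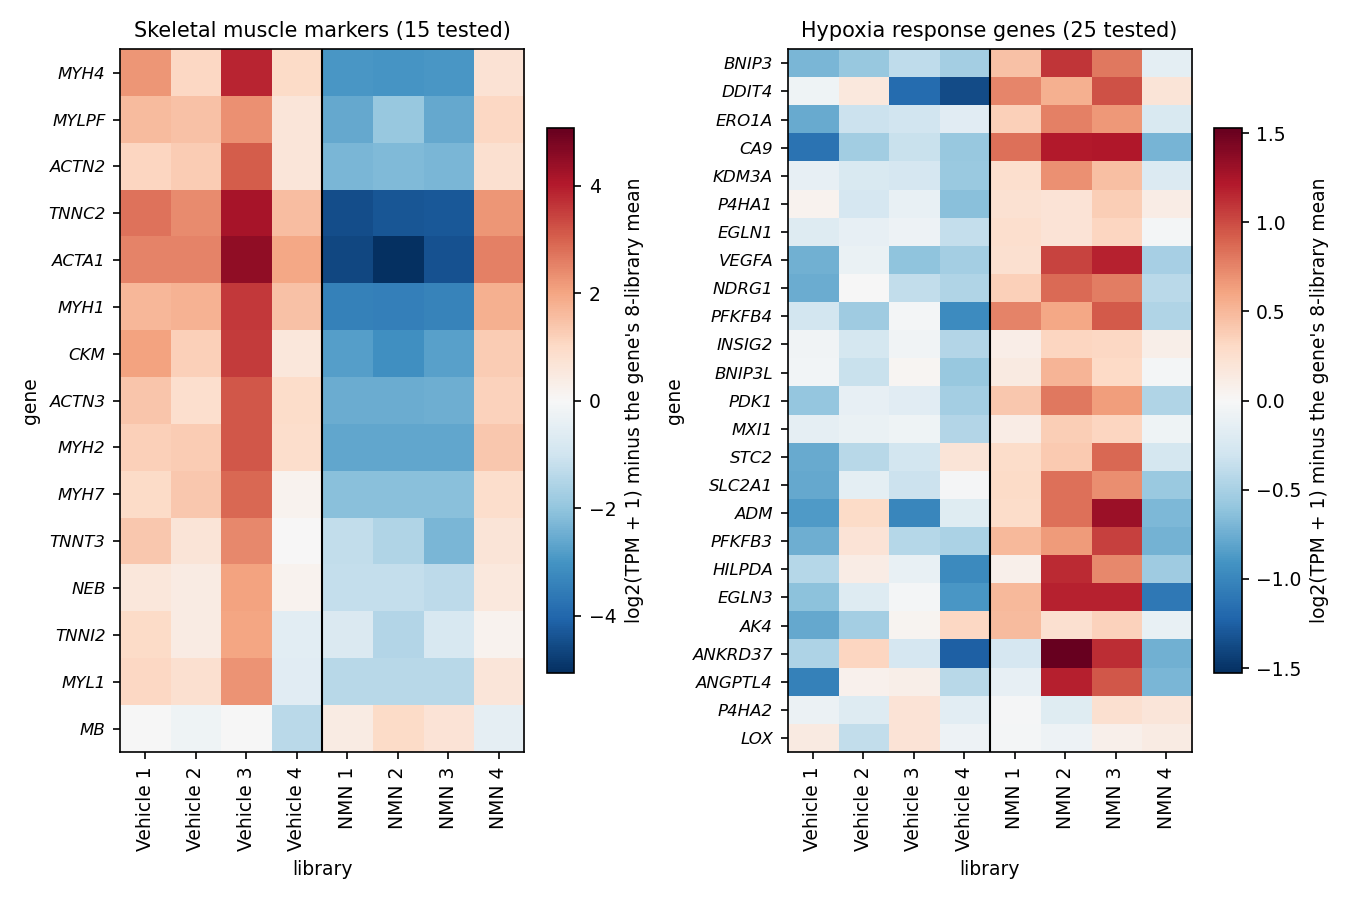
Colors show log2(TPM + 1) of each gene minus its 8-library mean, with genes in lines and the 8 tumors in columns, for the 15 tested skeletal muscle markers and the 25 tested hypoxia response genes. NMN 4 lies within the range of the Vehicle tumors in 14 of the muscle genes and in 19 of the hypoxia genes.

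Of 30 tested interferon response genes, 28 had the lower mean in NMN tumors, with a median log2 fold change of -0.33 (adjusted p = 1.3e-12 with the preset correlation, and adjusted p = 0.504 with an estimated correlation). Over all genes 0 passed, and adjusted over the list alone 1 did, OAS2. IFITM3, a restriction factor for viral entry, was at 362 ± 29.8 TPM against 497 ± 92.5 TPM, and the ubiquitin-like gene ISG15 at 45.3 ± 8.70 TPM against 71.4 ± 22.6 TPM. NMN 4 lay within the Vehicle range in 24 of the 30 genes and below it in 5, among them IFITM3. The interferon list score was 0.44 in Vehicle 4, from 0.020 to 0.10 in Vehicle 1 to 3, 0.060 in NMN 4 and from -0.28 to -0.20 in NMN 1 to 3. Without Vehicle 4 the interferon median was -0.22, and the list still passed by camera with the preset correlation (adjusted p = 1.0e-07). Of 18 antigen presentation genes, 14 had the lower mean, with a median of -0.23 (adjusted p = 9.8e-04, and adjusted p = 0.624 with an estimated correlation), among them the immunoproteasome genes PSMB9 and PSMB10 at log2 fold changes of -0.40 ± 0.13 and -0.38 ± 0.13. Their mean log2 fold change was -0.079, the list score was 0.027 in NMN 1 and 0.11 in NMN 3 against -0.073 to 0.18 in the Vehicle tumors, and its exact permutation p was 0.457. None of the 18 passed, adjusted over the list alone or over all genes. The median was -0.11 without Vehicle 4 and -0.16 without NMN 2. Without Vehicle 4 the antigen presentation list no longer passed (adjusted p = 0.0526, with a range from 1.8e-07 to 0.0526 over the settings with the preset correlation).

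Of 32 cell cycle genes, 26 had the lower mean in NMN tumors, with a median log2 fold change of -0.10 (adjusted p = 9.8e-04 with the preset correlation, and adjusted p = 0.794 with an estimated correlation). The mitotic kinase gene PLK1 was at 76.3 ± 3.89 TPM against 89.9 ± 5.59 TPM. The list's median was -0.15 without Vehicle 2, -0.066 without Vehicle 3, -0.030 without NMN 3 and -0.17 without NMN 4. Of 72 nuclear genes of oxidative phosphorylation, 50 had the lower mean, with a median of -0.036 (adjusted p = 0.0480, and adjusted p = 0.794 with an estimated correlation), or -0.010 without Vehicle 1 and -0.055 without Vehicle 4. NDUFC1, a subunit of complex I, and ATP5F1D, a subunit of ATP synthase, had log2 fold changes of -0.21 ± 0.08 and -0.26 ± 0.10. Adjusted over the list alone 0 genes passed in either list. The cell cycle list no longer passed without NMN 3 (adjusted p = 0.191, range from 8.3e-06 to 0.944 over the same settings), and the oxidative phosphorylation list without NMN 3, NMN 4, Vehicle 1 or Vehicle 2 (adjusted p = 0.170, 0.122, 0.262 and 0.482, range from 0.0012 to 0.482).

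**Figure D3:**
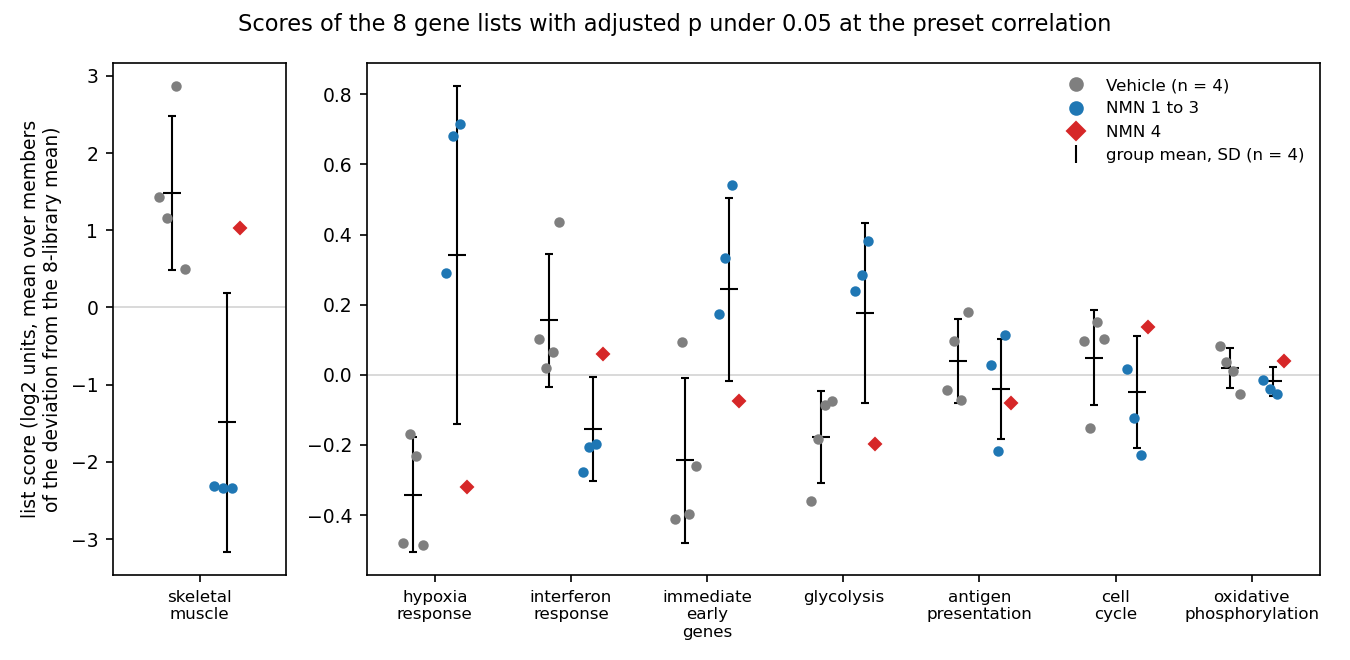
Each point is the score of 1 list in 1 tumor, in log2 units, for the 8 lists that passed with the preset correlation, and black bars give the mean and SD of 4 tumors per group. NMN 4 has a muscle score of 1.03 and a hypoxia score of -0.32, both within the range of the Vehicle tumors.

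Genes tied to invasion and spread did not pass as lists in the main test. Of 21 tested mesenchymal and EMT genes 10 had the higher and 11 the lower mean, with a median log2 fold change of -0.05 and a mean of 0.06 that differ in sign (adjusted p = 0.850). The fibronectin gene FN1 was at 37.9 ± 12.0 TPM against 20.1 ± 5.96 TPM, and the EMT transcription factor gene ZEB2 at 1.22 ± 0.375 TPM against 2.35 ± 0.639 TPM. The lists of 24 matrix proteases and inhibitors, 23 mediators of breast cancer metastasis and 27 epithelial junction genes had medians of 0.04, 0.13 and 0.12 (adjusted p = 0.562, 0.177 and 0.0865), and adjusted over the list alone 1 gene of these 4 lists passed, the urokinase receptor gene PLAUR, at 32.5 ± 4.87 TPM against 19.9 ± 3.60 TPM. With 1 tumor left out the median of the EMT list ran from -0.12 (without Vehicle 2) to 0.059 (without Vehicle 3) and that of the protease list from -0.030 (without NMN 3) to 0.080 (without Vehicle 3). For the metastasis list it ran from 0.069 (without NMN 1) to 0.26 (without Vehicle 2), and for the junction list from 0.093 (without Vehicle 4) to 0.19 (without NMN 2). Without NMN 4 the metastasis list passed with higher levels (adjusted p = 0.0212, range from 0.0212 to 0.728 over the settings with the preset correlation, and adjusted p = 0.354 with an estimated correlation). With library weights the metastasis list (adjusted p = 0.0356) and the epithelial junction list (adjusted p = 0.0293, range from 0.0293 to 0.499) passed, both with higher levels, and neither did with an estimated correlation (adjusted p = 0.483 and 0.577). The matrilysin gene MMP7 was at 81.1 ± 56.7 TPM against 23.5 ± 13.2 TPM, and the galectin gene LGALS3 at 819 ± 84.4 TPM against 599 ± 87.1 TPM. CLDN4, of tight junctions, and ESRP2, an epithelial splicing regulator, had log2 fold changes of 0.52 ± 0.14 and -0.35 ± 0.11.

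Cell type markers did not pass as lists in the main test, apart from skeletal muscle. Values are of human genes, and whether these transcripts came from mouse cells or from the human tumor cells was not tested. Fibroblast, pericyte or smooth muscle, myeloid, endothelial, adipocyte and Schwann cell lists, with 12, 8, 9, 5, 7 and 4 tested genes, had medians of -0.29, -0.15, -0.13, 0.05, 0.29 and -0.16 (adjusted p = 0.0865, 0.0865, 0.214, 0.487, 0.487 and 0.164). With 1 tumor left out, in the same order, the lowest medians were -0.46, -0.35, -0.16, -0.066, 0.15 and -0.34 and the highest -0.22, -0.037, -0.078, 0.14, 0.41 and -0.071. The lowest were without NMN 4, except for the myeloid (NMN 3), endothelial and adipocyte (both Vehicle 4) lists, and the highest without Vehicle 4, NMN 2, NMN 1, Vehicle 3, Vehicle 1 and NMN 2. With lower levels the fibroblast list passed without NMN 4 or without Vehicle 1 (adjusted p = 0.0088 and 0.0180, range from 0.0073 to 0.797) and the pericyte list without NMN 4 (adjusted p = 0.0016, range from 0.0016 to 0.944), and neither with an estimated correlation. The fibroblast list also passed with library weights, with the replicate block and without the filter, and the myeloid list with the muscle covariate (adjusted p = 3.3e-05, range from 3.3e-05 to 0.896), but neither with an estimated correlation under any setting. Within the fibroblast list the collagen genes COL6A1 and COL6A2 had log2 fold changes of 0.80 ± 0.18 and 0.69 ± 0.18, against -0.58 ± 0.19 for PDPN, and adjusted over the list alone 2 members were higher and 3 lower. DES, the desmin gene of the pericyte list, which striated muscle also expresses, was at 0.55, 0.67 and 0.60 TPM in NMN 1 to 3, at 105 TPM in NMN 4 and at 120.0 ± 87.7 TPM in Vehicle tumors, and the endothelial receptor gene KDR at 3.94 ± 0.975 TPM against 1.83 ± 0.633 TPM, and each was the 1 member of its list to pass adjusted over the list alone. The erythroid list had 2 tested genes and was not tested.

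Across all tested genes NMN 4 correlated with the Vehicle tumors at a mean Pearson r of 0.982 and with the other NMN tumors at 0.978, while NMN 1, NMN 2 and NMN 3 correlated with each other at 0.987 and with the Vehicle tumors at 0.972. The Vehicle tumors correlated with each other at a mean of 0.977. Singly, NMN 4 correlated with Vehicle 1 to 4 at 0.988, 0.983, 0.985 and 0.971 and with NMN 1 to 3 at 0.980, 0.976 and 0.979. These are correlations across genes, which are not independent replicates. The first principal component, with 30.7% of the variance, placed NMN 1 to 3 between 21.3 and 24.6, NMN 4 at -9.69 and the Vehicle tumors between -22.6 and -7.08. The second, with 26.7%, divided the Vehicle tumors. It placed Vehicle 1 at -21.6, Vehicle 3 at -14.5 and NMN 4 at -18.3, against 10.7 for Vehicle 2 and 35.2 for Vehicle 4. NMN 1 to 3 lay between -0.624 and 7.60 on it.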

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

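The tests of a wrong label, of muscle tissue, of muscle as a covariate and of NMN treatment were chosen after the results were seen. A tumor far from the other 3 of its group was found in 10 of the 146 groups of 4 examined, where chance gives about 1 in 20. NMN 4 was the far tumor in 7, each a gene expressed in muscle or the muscle list score, so these are 1 pattern. The groups examined are also not independent of each other.

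The gap of NMN 4 above the other 3 NMN tumors, as a share of the group's range on the log2 scale, was 0.985 for MYH4, 0.982 for ACTN2, 0.967 for TNNC2, 0.908 for ENO3, 0.913 for ACTA1 and 0.982 for DES, and 0.992 for the score of the skeletal muscle list. The same share was 0.837 for CAMK1 in Vehicle 1, which lay low, and 0.831 for JUN and 0.833 for COL6A1 in NMN 3, which lay high.

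The skeletal muscle markers were low in 3 of the 4 NMN tumors and present in the other 5 tumors. A candidate explanation is skeletal muscle tissue in those 5 samples: over the 12 markers with at least 5 TPM in every Vehicle tumor, Vehicle 3 exceeded the other Vehicle tumors by a median of 2.04 on the log2 scale with an interquartile range of 0.494, so the markers moved in nearly 1 ratio, with ACTA1 and TNNC2 the most abundant at 1024 and 645 TPM in Vehicle 3. None of the 15 genes is in another list, but MB and TNNI2 were expressed in NMN 1 to 3 as well, MB at a higher mean level than in the Vehicle tumors. Whether the transcripts are of mouse or human origin was not tested. An effect of NMN treatment stays open, with an exact permutation p of 0.0571 for the list score.

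The hypoxia response genes were high in the same 3 NMN tumors, so that hypoxia and muscle levels split the tumors alike, and with muscle as a covariate the hypoxia median was 0.20, where the median of all genes was 0.15. Differences in scaling, GC content or gene length as the whole source are argued against, since the lowest median log2 fold change under these corrections was 0.67. Over the 27 genes called higher without NMN 4, its median position was 0.014. The scale runs from 0, the Vehicle mean, to 1, the mean of NMN 1 to 3. These genes were chosen by the difference of NMN 1 to 3 from the same Vehicle values. A position near 0 can therefore arise from anything that sets those 3 tumors apart, NMN or not. A wrong label or a tumor without a response would also give it. In MSLN, at 1.68 the highest of the 4 among these 27 genes that lay past 0.5, NMN 4 lay with the NMN tumors. It did so in all 6 MTRNR2L genes too, below the Vehicle range and a median of 4.21 Vehicle SD under the Vehicle mean. MSLN, MTRNR2L1, MTRNR2L6 and MTRNR2L9 were named for a small p over all 4 NMN tumors. Such a choice favors genes where NMN 4 lies with its group, and the MTRNR2L genes may share reads. A wrong label and a tumor without a response are therefore neither shown nor excluded. An effect of NMN treatment stays open, with an exact permutation p of 0.0857 for the list score over all 4 NMN tumors.

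All 6 tested MTRNR2L genes were lower in the 4 NMN tumors, NMN 4 included, without overlap. The family made up 3.43% ± 0.70 of all TPM against 5.25% ± 0.75 (SD, n = 4). The groups nearly met, with a share of 4.48% in NMN 2 and 4.60% in Vehicle 2. MTRNR2L2, the most abundant of the 6, was at 28198 TPM in NMN 2 and 28504 TPM in Vehicle 2. Since reads cannot be assigned to single members with certainty, the 6 genes are not 6 separate results. Reads of the mitochondrial 16S ribosomal RNA are a candidate source that cannot be told apart from the genes' own transcripts. Identity to this RNA was 93.0% for MTRNR2L8, 90.7% for MTRNR2L9, 88.3% for MTRNR2L1, 84.2% for MTRNR2L6, 81.6% for MTRNR2L2 and 79.9% for MTRNR2L10. MTRNR2L8 was at 11229 and 17400 TPM in NMN and Vehicle tumors, and MTRNR2L10 at 19.3 and 27.4 TPM. The transcripts compared for MTRNR2L2 and MTRNR2L9 hold only 87 and 75 nt. These identities neither exclude nor require shared reads, and the mitochondrial genes were not analysed here. With muscle as a covariate the median log2 fold change of -0.65 was -0.70, but muscle levels nearly follow the groups apart from NMN 4, so this fit rests mainly on 1 tumor. In NMN 4 the muscle list made up 0.0700% of TPM, within the Vehicle range, and the family 3.21%, below it. That argues against muscle tissue as the carrier of mitochondrial RNA for this tumor only. An effect of NMN treatment may be involved, with an exact permutation p of 0.0286 for the share, the smallest that 4 against 4 allow, in a family singled out after its values were seen. After quantile normalization 5 of the 6 genes were lower.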

How the results depend on the processing

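The removal of the MTRNR2L genes, the muscle covariate, the GC and length correction and the permutation of list scores were chosen after the data were seen, and a planned removal of mitochondrial genes was not run because none was among the genes analysed. SIRT1 stayed between 0.02 and 0.16 on the log2 scale and SHC1 between -0.29 and -0.04, with adjusted p of at least 0.785 and 0.460, under every setting run. The count of genes past the threshold was 0 with limma under all settings except library weights (54 genes, 33 of them shared with the 54 called without NMN 4), the replicate block, and the removal of Vehicle 3 or NMN 4, with a range from 0 to 54 over the libraries left out. With library weights, which gave NMN 1 a weight of 3.39, 1492 genes had an unadjusted p under 0.05 and 13 lists passed; with 1 library left out these counts ran from 568 (without NMN 3) to 1276 (without NMN 4) and from 7 (without NMN 3) to 14 (without NMN 4). The labels do not say whether equal replicate numbers pair tumors, and the values gave no sign of it. Deviations of same-numbered tumors from their group means correlated across genes at 0.03, 9.4e-04, -0.03 and -0.12, and no tumor correlated best with its own number. Such correlations cannot exclude a pairing. As a replicate block the numbers gave 2 genes, HSD11B2 and FCGR3B. The oxidative phosphorylation list (-0.036) then no longer passed (adjusted p = 0.0621), the fibroblast list passed, and no other list changed its call. The split of genes with an unadjusted p under 0.05 was 697 higher and 626 lower after the GC and length correction, and 525 and 365 after removal of the MTRNR2L genes. With an estimated correlation 0 lists passed. By exact permutation of list scores 0 passed too, which its smallest possible p of 0.0286 nearly fixed in advance. The medians, which the correlation does not alter, were -3.02 for skeletal muscle, 0.70 for hypoxia, -0.33 for interferon and 0.45 for immediate early genes. They were 0.37 for glycolysis, -0.23 for antigen presentation, -0.10 for cell cycle and -0.036 for oxidative phosphorylation. The oxidative phosphorylation list also missed the threshold with a pseudocount of 5 (-0.035), a filter at 5 TPM (-0.036), median-of-ratios scaling (-0.041) and quantile normalization (-0.050), and ranged from -0.055 to -0.010 over the libraries left out, where antigen presentation ranged from -0.31 to -0.11 and cell cycle from -0.17 to -0.030. Of the 32 lists that did not pass in the main test, 15 passed under some other setting with the preset correlation and 0 under any with an estimated one. The skeletal muscle median was -5.06 with a pseudocount of 0.1 and -1.61 with one of 5. The muscle covariate, which nearly separates NMN 1 to 3 from the other tumors, moved the median of all genes to 0.15. Under it camera turned the direction of glycolysis (-0.015), hypoxia (0.20) and immediate early genes (0.26), and skeletal muscle (0.050), which is the covariate itself, and cell cycle (0.13) no longer passed; DES (0.044), NAMPT (0.31), NMNAT1 (0.32) and NMNAT3 (0.16) changed sign. NAMPT also did so over the libraries left out, from -0.12 to 0.12, as did NMRK1, from -0.15 to 6.2e-04. Apart from the fits with fewer tumors or genes, the cause was not tested. Among single named genes 41 values moved past the threshold under some setting and 9 changed sign, while 1267 did neither. The depth of the libraries is unknown, so what depth limits cannot be given.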

Other observations

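The test of the metallothionein genes was chosen before its result was seen, while the choice to look at them and their fits with 1 tumor left out came after the data were seen. KRT8, a keratin of luminal cells, was at 834 ± 88.8 TPM in NMN tumors against 415 ± 145 TPM in Vehicle tumors, with no overlap and a log2 fold change of 1.07 ± 0.21 (adjusted p = 0.221). It was the 1 luminal gene of 16 that passed adjusted over the list alone, and the list did not pass (adjusted p = 0.156). KLK8, a protease of the squamous differentiation list, was at 519.8 ± 91.3 TPM against 328 ± 57.5 TPM, a log2 fold change of 0.66 ± 0.15, the 1 member that passed adjusted over the list alone, and 20 of the 26 tested genes of that list had the higher mean (adjusted p = 0.0865). Basal markers, at a median of -0.11 over 18 genes, did not pass (adjusted p = 0.256), and their median ran from -0.34 without Vehicle 1 to 0.13 without Vehicle 4. That of the squamous list ran from -0.056 without Vehicle 1 to 0.38 without NMN 4. With 1 tumor left out and the preset correlation, the squamous list passed without Vehicle 2, Vehicle 4 or NMN 4, the luminal list without Vehicle 1, Vehicle 3 or NMN 1, and the basal list without Vehicle 1 or Vehicle 3. The squamous list, at a median of 0.13, also passed with a filter at 5 TPM (adjusted p = 0.0427) and with library weights (median 0.44, adjusted p = 7.7e-06), and with lower levels under the muscle covariate (median -0.79, adjusted p = 6.7e-14), with 0.943 the highest adjusted p over the settings. The luminal and basal lists also passed under that covariate, and none of the 3 passed with an estimated correlation under any setting. The other 15 lists did not pass either in the main test, with adjusted p from 0.0865 for DNA double-strand break repair to 0.820 for cholesterol synthesis. Under other settings 7 of them passed with the preset correlation and 0 with an estimated one (smallest adjusted p = 0.331). With the preset correlation repair genes passed as lower without Vehicle 2, NMN 1 or NMN 4 and after the GC and length correction (adjusted p from 0.0085 to 0.587 over all settings). Ribosomal protein genes passed as higher without Vehicle 2 or NMN 4 and lower under the muscle covariate (8.9e-07 to 0.831), and NF-kB genes higher without Vehicle 2 or with library weights and lower under that covariate (8.2e-06 to 0.943). Heat shock genes passed as higher without Vehicle 1 or Vehicle 2 (0.0140 to 0.977), and YAP and TAZ targets without Vehicle 4 (0.0333 to 0.963). Fatty acid synthesis genes passed as higher without Vehicle 3 or NMN 3 and under the muscle covariate (3.3e-05 to 0.525), and stress response genes without NMN 4 (0.0406 to 0.616). The list of the unfolded protein and integrated stress response had an exact permutation p of 0.0286, the smallest of the 40, which adjusted to 0.571.

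Among the 54 genes called without NMN 4, 11 were in the skeletal muscle list and 7 in the hypoxia list.

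Of the 35 ways to split the 8 tumors into 4 and 4, the real split called 0 genes, with 9 the highest of the others, and since all 35 call at least 0 this count says nothing about chance. For genes at an unadjusted p under 0.05, 11 of the 35 splits gave at least the real 927, with 2048 the highest of the others, and for lists with the preset correlation 30 of the 35 gave at least the real 8, with 20 the highest of the others. Chance therefore cannot be excluded for the latter 2 counts. The split with 2048 genes set Vehicle 2 with NMN 1, NMN 2 and NMN 3 against Vehicle 1, Vehicle 3, Vehicle 4 and NMN 4. The next highest, with 1649 and 1556 genes, set Vehicle 1, Vehicle 3 and NMN 4 with NMN 1 or NMN 3 against the rest. In each of these NMN 4 stood with Vehicle 1 and Vehicle 3 and apart from Vehicle 2. With Vehicle 1, Vehicle 3 or Vehicle 4 in place of Vehicle 2 beside NMN 1 to 3, the splits gave 1182, 825 and 1015 genes.

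The 4 tested metallothionein genes were examined for a joint shift, as a hypothesis. Of them 3 had the higher mean in NMN tumors, with a median log2 fold change of 0.24, and camera with an estimated correlation gave p = 0.212, against an exact permutation p of 0.143 for their score. Without NMN 4 the median was 0.43, camera gave p = 0.0487 and the exact permutation p = 0.0286, the smallest that 3 against 4 allow, and MT1X was called, with a log2 fold change of 1.31 (limma, adjusted p = 0.0087). Over all fits with 1 tumor left out the median ran from 0.086 (without Vehicle 2) to 0.43 and the camera p from 0.0487 to 0.695 (without NMN 2), so a joint shift was neither shown nor excluded.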
